A study of Danio rerio with 6 samples.

How the data were processed

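Total RNA of whole kidney marrow was made into stranded libraries after removal of ribosomal RNA, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.17.1.14, STAR 2.5.3a, featureCounts 1.5.2, DESeq2 1.14.1 and the genome build GRCz10, without the role of each. The settings of the authors' counting, its strand option included, are not given in the sources used here, so genes with near-identical copies and overlapping genes are uncertain. The deposited signal per gene is a normalized count, named by the authors as made with DESeq2. Division of the reads by 1 size factor per sample was inferred from the whole multiples described below. The authors' deposited table gives a shrunken and an unshrunken log2 fold change, of which the unshrunken is printed unless stated. The shrunken values can be far smaller, such as −1.60 against −2.45 for il7 and −1.85 against −5.24 for cxl34b.11. That table also holds the authors' p-value with its adjusted value, and the deposited Wald statistic, a score that was not used.

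The table has 32267 features, of which 6019 were at 0 in all 6 libraries. Symbols came from a table of gene names, which matched 26433 of the features (81.9%), and are written as given there, so some are in capitals. Every value was a whole multiple of the smallest positive value of its column, within 1e-06 of a read. The totals of these multiples gave the depth: 46120889, 39478321 and 38901066 reads for control 1, 2 and 3 and 34496353, 35854285 and 39265305 reads for il7 mutant 1, 2 and 3. The multiples were used for depth and for the reads of il7, and no count model was run on them, so a test on a log scale is the main one.

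Groups and replicate numbers were taken from the sample titles. Genes with a mean normalized count of at least 10 over the 6 samples were kept. The groups were compared on log2(normalized count + 1) with limma 3.58.1 in R 4.3.3, with a variance trend in the empirical Bayes step and Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of low genes. Gene sets were tested with limma's camera at a preset correlation of 0.01, for lists with at least 5 fitted members, adjusted over the 27 lists tested of 28. IGHMBP2 matched the immunoglobulin name pattern and was left out, since it is no immunoglobulin segment. No pair of libraries agreed within sampling noise: the smallest chi-square per degree of freedom was 90.8.

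The lists, the main tests and all other alternatives were fixed before the data were examined, while the 2 alternatives on the oocyte-rich libraries, the use of no filter together with an estimated correlation and the tests of explanations were chosen afterwards. Named genes were il7, up to 12 higher and 12 lower genes past the adjusted threshold with groups that do not overlap and a symbol that is no clone name, the 3 members with the smallest p in each list, and 20 genes named in advance, of which 14 were fitted. Since limma called 0 genes, the second part named none. It was applied to the authors' deposited table instead, after the values were seen. Some genes that these rules name are not reported here. The oocyte, testis, AP-1 and heat shock parts of 2 lists were also chosen after the values were seen.

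The steps were tested on simulated values for the comparison of il7 mutant with control, drawn for the real genes with known changes. Each gene was drawn independently of the others. With each gene's own observed spread, 20644 genes were fitted, and limma recovered 0 of 66 genes changed 2-fold, 17 of 63 changed 4-fold and 33 of 65 changed 16-fold, with 8 unchanged genes called. With the median spread for every gene, 20761 genes were fitted, and 7 of 66, 53 of 65 and 65 of 65 were recovered, with 7 unchanged genes called. Alternatives covered the pseudocount, the filter, the scaling, the variance model, a replicate block, each replicate left out, the thresholds and the set test.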

Results

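RNA was sequenced from unsorted whole kidney marrow of zebrafish, the main blood-forming tissue of adult teleosts. There were 2 groups of 3 libraries each, control fish and fish carrying an internal deletion of exons 2 to 4 of il7, which encodes the cytokine interleukin 7. The comparison asked what role il7 has in the development of lymphocytes. The libraries held between 34496353 and 46120889 reads assigned to genes. Nothing in the labels says how many fish went into a library, so p-values measure only the spread between these samples, which may be technical.

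The targeted gene il7 (ENSDARG00000092045) was lower in each mutant library than in any control library. Its normalized count was 69.7 ± 17.5 (SD, n = 3) in controls and 12.8 ± 7.64 (SD, n = 3) in mutants, so 18.3% of the control mean was left. The control libraries held between 52 and 114 il7 reads and the mutant libraries between 4 and 18. A two-sided exact permutation test of il7 gave p = 0.1, the smallest that 3 against 3 samples can give. On the log2(normalized count + 1) scale the limma change was −2.55 (SE 0.66), with an adjusted p of 1.00 over all genes, and −1.93 without il7 mutant 3. In the authors' deposited table il7 had a log2 fold change of −2.45 (−1.60 shrunken) and an adjusted p of 0.0403. The counts are per gene, so they do not show which exons the remaining reads came from.

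**Figure D1:**
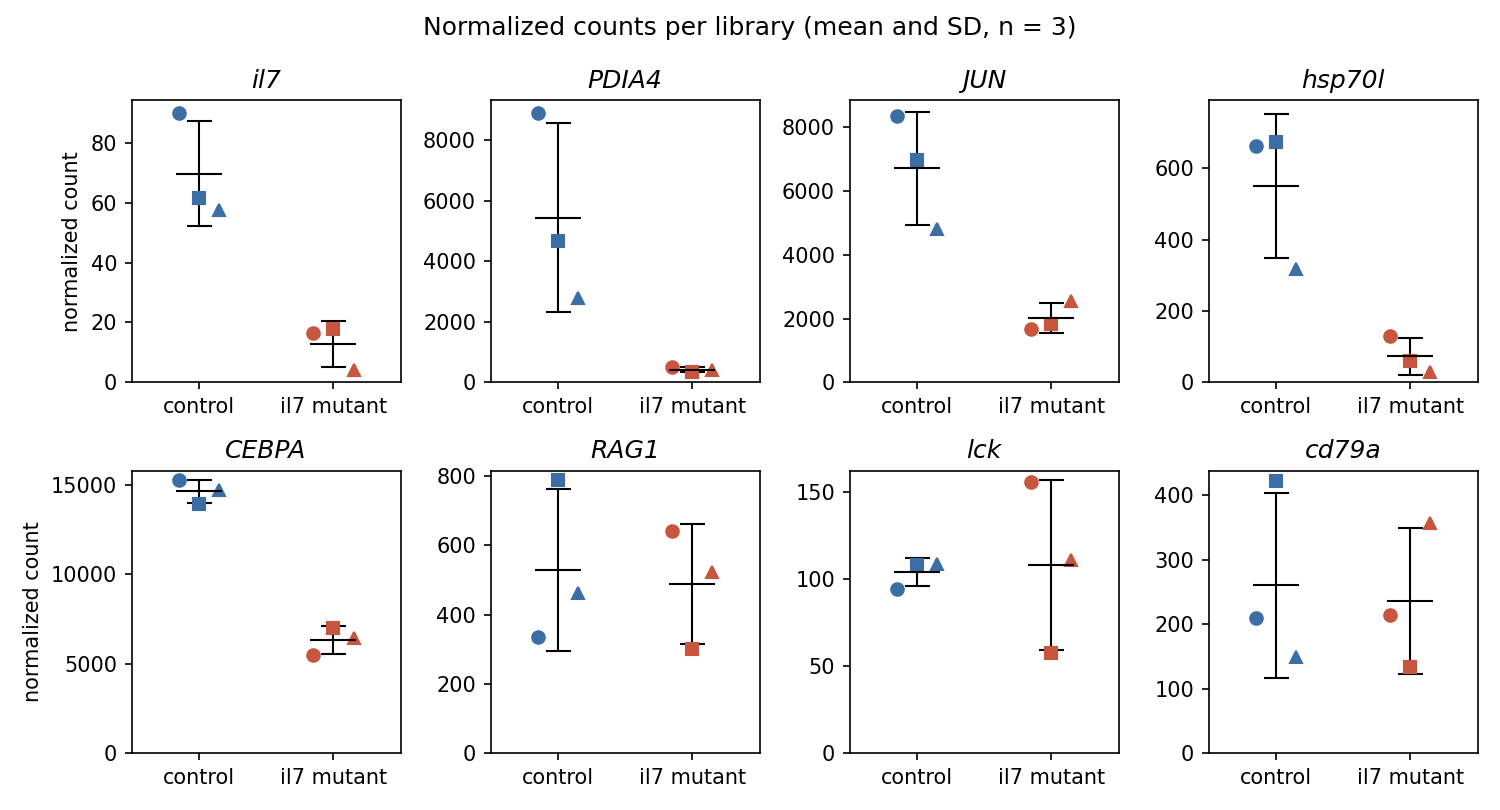
Normalized counts of 8 genes in the 3 control (blue) and 3 il7 mutant (red) libraries, with replicate 1 as circles, 2 as squares and 3 as triangles; the bars are the mean and SD. The il7, PDIA4, JUN, hsp70l and CEBPA values of the groups do not overlap, whereas those of RAG1, lck and cd79a do.

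None of the lymphocyte genes named here passed the limma test with all 6 libraries. RAG1, a subunit of the recombinase that assembles antigen receptor genes, had 529 ± 235 normalized counts in controls and 488 ± 174 in mutants (SD, n = 3), and RAG2 had 349 ± 119 and 343 ± 96.3 (SD, n = 3). The log2 change was −0.10 (SE 0.43) for RAG1 and −0.00 (SE 0.39) for RAG2. The T cell kinase gene lck changed by −0.05 (SE 0.45), the B cell receptor component cd79a by −0.12 (SE 0.53) and the heavy chain gene ighm by −0.29 (SE 0.35). These errors leave room for changes of either sign. The receptor gene il7r, which encodes the chain that binds interleukin 7, stood at 71.6 ± 11.7 and 79.1 ± 14.5 normalized counts (SD, n = 3). Other genes of the common gamma chain and JAK-STAT list had log2 changes of −0.54 (SE 0.29) for il2rga and −0.38 (SE 0.24) for jak3. In the same list stat5a had −0.42 (SE 0.52), stat5b −0.11 (SE 0.22), il2rb −0.17 (SE 0.41) and crlf2 −1.58 (SE 0.64). ZAP70 and cd4-1 had −0.87 (SE 0.46) and −0.73 (SE 0.54). The T cell list members with the smallest p went both ways, and those of the B cell list were higher. The T cell receptor component cd247 had 86.6 ± 54.3 normalized counts in controls and 262 ± 138 in mutants (SD, n = 3), a log2 change of 1.77 (SE 0.72) and of 1.03 without control 1. Its count was 421 in il7 mutant 3 against 191 and 175 in the other mutants. The chemokine receptor CXCR5 had 12.2 ± 3.50 and 53.8 ± 33.3 (SD, n = 3), a log2 change of 1.89 (SE 0.62). The changes were −1.20 (SE 0.47) for foxp3a, −0.88 (SE 0.41) for RUNX3, 0.70 (SE 0.38) for cd79b and 0.77 (SE 0.35) for BCL6B.

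As sets, 21 of 26 fitted T cell genes had a negative sign (adjusted p = 0.134 in limma's camera test), as had 15 of 19 B cell genes (adjusted p = 0.734) and 14 of 21 V(D)J recombination and lymphoid precursor genes (adjusted p = 0.913). The immunoglobulin segments, with 7 of 12 lower, had an adjusted p of 0.913. Not every listed symbol was found. The T cell list gave 46 symbols and matched 29 features, and the B cell list gave 34 and matched 19. The markers cd3e and ighz had no match, and cd8a fell below the filter. Only 2 T cell receptor segments passed the filter on low values, too few for the set test. With no filter that list was tested and passed as lower (adjusted p = 0.0356), but not with an estimated correlation as well (adjusted p = 0.733), a test added after seeing the data. The common gamma chain and JAK-STAT genes (adjusted p = 0.129), the gamma chain family cytokines (adjusted p = 0.112), which include il7 itself, and the plasma cell genes (adjusted p = 0.221) did not pass either. Some of these calls depended on single libraries. Without il7 mutant 3, the T cell list (adjusted p = 0.0286), the common gamma chain and JAK-STAT list (adjusted p = 0.0388) and the cytokine list (adjusted p = 0.0388) passed as lower. The common gamma chain and JAK-STAT list also passed as lower without control 1 (adjusted p = 0.0357) and with array quality weights (adjusted p = 0.00779), the cytokine list without il7 mutant 1 (adjusted p = 0.0474), and the plasma cell list without control 3 (adjusted p = 0.0479). The B cell, V(D)J and immunoglobulin lists passed in none of the alternatives. With an estimated correlation 0 of the 27 lists passed (smallest adjusted p = 0.357). Adjusted over the list alone, 0 genes passed in each of these lists except the plasma cell list, where PDIA4 passed as lower.

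Across the genome, limma called 0 of 20782 fitted genes at an adjusted p under 0.05, against 723 at an unadjusted p under 0.05, where 1039 would be expected by chance. The smallest adjusted p was 0.288, and lay between 0.137 without il7 mutant 1 and 0.683 without il7 mutant 2 when single libraries were left out. It was 0.0634 with array quality weights and 0.0916 with the oocyte-rich libraries, control 1 and il7 mutant 2, as a model term. The 3 mutant values lay wholly above or below the 3 control values for 1651 genes, 7.94% of those fitted. Chance gives 10% over all ways to split the libraries, also those that keep the oocyte-rich libraries together. Other splits that put these in opposite groups, as the real one does, gave between 792 and 1304 such genes. They gave between 227 and 466 genes at an unadjusted p under 0.05, against 723. These splits are too few for a p-value. The authors' deposited table holds 112 genes at an adjusted p under 0.05, with 45 higher and 67 lower in the mutants. Of these, 111 were fitted here, and all 111 had the same sign and an unadjusted limma p under 0.05, while 0 passed the adjustment. Both analyses use the same libraries, so this overlap is not independent evidence.

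Because limma called 0 genes, the genes described next were taken from the authors' deposited table, a choice made after the values were seen. The naming rule left out features with no symbol or a clone name, some with larger changes than those named. The largest rise, 8.30 for si:dkey-103k4.3, went with 0.370 ± 0.641 normalized counts in controls and 109 ± 33.6 in mutants (SD, n = 3). The largest fall, −8.47 for ENSDARG00000104174, went with 729 ± 464 and 2.00 ± 2.64 (SD, n = 3). By that rule, the lower genes with the largest change in the authors' deposited table included prkacbb, a catalytic subunit of protein kinase A. There prkacbb had a log2 fold change of −5.49 (−3.14 shrunken) and an adjusted p of 2.1e-09. Its normalized counts were 471 ± 235 in controls and 10.6 ± 7.96 in mutants (SD, n = 3). PDIA4, a protein disulfide isomerase of the endoplasmic reticulum, had −3.69 in the authors' deposited table, with 5447 ± 3128 normalized counts in controls and 423 ± 76.1 in mutants (SD, n = 3). The authors' deposited table also held CREB5 at −3.57, the heat shock genes hsp70l at −2.91 and HSPA2 at −2.67, nkl.3, a gene of the antimicrobial NK-lysin family, at −3.58, and G6PC1, a glucose-6-phosphatase, at −3.41. Further lower genes in the authors' deposited table were cxl34b.11, pimr171, adra2db, ppp1r3c2a and emp1, at −5.24, −4.97, −3.85, −3.35 and −2.83.

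Among the higher genes, the authors' deposited table gave hpxb, a hemopexin, a log2 fold change of 4.78 and an adjusted p of 2.5e-08. Its normalized counts were 11.2 ± 3.17 in controls and 307 ± 200 in mutants (SD, n = 3). CRACR2A had 3.48 in the authors' deposited table, with 11.6 ± 7.39 and 127 ± 7.98 normalized counts (SD, n = 3). The Wnt receptor gene FZD8 had 2.63 in the authors' deposited table, and the gap junction gene GJA5 had 2.15. Further higher genes by the same rule in the authors' deposited table were C20H6orf58 (4.61), SARM1 (3.35), RALGPS1 (2.82), CADM1 (2.66), FLRT2 (2.58), OLFM2 (2.38) and SLC25A48 (2.35). C20H6orf58 stood at 12.97 in il7 mutant 1 against 188 and 254 in the other mutants. Several named genes, such as hsp70l, nkl.3, pimr171 and cxl34b.11, belong to families of similar copies, so their counts are uncertain.

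Single libraries weighed on several of these folds. Of the 23 genes that the rule took from the authors' deposited table, none changed sign when 1 library was left out. On the limma scale, 10 of these genes moved by over 1.5 times. G6PC1 went from −2.82 to −2.03 without control 2, which held 220 of its normalized counts against 34.7 and 48.8 in the other controls. The nkl.3 change of −3.29 became −2.56 without control 2, −3.99 without control 3 and −2.70 without il7 mutant 2. Without il7 mutant 2, prkacbb stood at −4.83, emp1 at −3.73, hpxb at 5.08 and SLC25A48 at 2.79. C20H6orf58 stood at 5.01 without il7 mutant 1 and 2.91 without il7 mutant 3, and RALGPS1 at 3.21 without il7 mutant 3. SARM1 stood at 4.50 without control 3 and ppp1r3c2a at −2.33 without control 1.

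Immediate early and stress genes, which respond within minutes to stimulation or damage, were lower as a set, with 23 of 28 fitted members negative and a median log2 change of −0.48 (camera adjusted p = 3.0e-06). The adjusted p was 0.357 with an estimated correlation. Adjusted over the list alone, 2 members passed, JUN and hsp70l, both lower, against 0 over all genes. JUN, a subunit of the AP-1 transcription factor, had 6701 ± 1780 normalized counts in controls and 2011 ± 471 in mutants (SD, n = 3). JUND had 1384 ± 115 and 735 ± 210 (SD, n = 3). The list level was highest in control 1. Its 7 fitted AP-1 and dual-specificity phosphatase genes had levels of 0.47, 0.59 and 0.46 log2 units in controls and −1.11, −0.55 and −0.23 in mutants. The level of its 10 fitted heat shock genes, a median over genes, overlapped between the groups, at 0.42, 0.31 and 0.12 in controls and −0.08, 0.24 and −0.67 in mutants. Single heat shock genes did not overlap, such as hsp70l and HSPA2, of which HSPA2 was not in the list.

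Natural killer and cytotoxic genes were lower as a set, with 17 of 21 negative and a median log2 change of −0.40 (camera adjusted p = 6.1e-04). The adjusted p was 0.740 with an estimated correlation, and 0 members passed when adjusted over the list alone. The perforin genes prf1.2 and prf1.3 had 183 ± 34.6 and 118 ± 36.4 normalized counts in controls and 72.7 ± 10.9 and 50.01 ± 0.531 in mutants (SD, n = 3).

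Of the myeloid lists, neutrophil genes did not pass as a set with all 6 libraries (adjusted p = 0.147). The list passed as lower in 5 of 19 alternatives, with adjusted p of 1.8e-04 with array quality weights, 0.0179 without control 1, 0.0479 without control 3, 0.00972 without il7 mutant 2 and 2.6e-04 without both control 1 and il7 mutant 2. Its adjusted p was 0.993 with an estimated correlation. One member, CEBPA, a transcription factor of granulocyte development, passed as lower when adjusted over the list alone, with 14647 ± 654 normalized counts in controls and 6319 ± 769 in mutants (SD, n = 3). Macrophage and monocyte genes (adjusted p = 0.913), MHC class II genes (adjusted p = 0.288), mast cell and eosinophil genes (adjusted p = 0.629) and thrombocyte genes (adjusted p = 0.533) did not pass. The thrombocyte list passed as higher without control 2 (adjusted p = 0.00163). With all 6 libraries its adjusted p was 0.993 with an estimated correlation, and its direction was higher in 16 of 19 alternatives.

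The other 5 passing lists were higher in the mutants. Liver and pancreas genes had 24 of 28 members positive (camera adjusted p = 3.0e-06, and adjusted p = 0.794 with an estimated correlation), and apoa1b, an apolipoprotein, stood at 107 ± 74.8 and 1052 ± 748 normalized counts (SD, n = 3). The groups overlapped, with apoa1b at 188.6 in il7 mutant 1 and 189.7 in control 3, and its log2 change was 3.04, or 4.03 without il7 mutant 1. Endothelial and stroma genes had 18 of 26 positive (camera adjusted p = 8.1e-04, and adjusted p = 0.794 with an estimated correlation). Their members include col1a1a, a collagen, at 14672 ± 6699 and 30040 ± 8381 (SD, n = 3), with overlapping groups. Erythroid genes had 26 of 33 positive (camera adjusted p = 0.00243, and adjusted p = 0.991 with an estimated correlation). Muscle genes had 11 of 12 positive (camera adjusted p = 0.0161, and adjusted p = 0.991 with an estimated correlation), with the muscle actin actc1b at 12459 ± 17229 and 27566 ± 35307 (SD, n = 3). The actc1b values overlapped, and its log2 change of 1.38 was 0.29 without il7 mutant 1, 0.67 without control 2 and 2.61 without control 3. Stem and progenitor genes had 13 of 20 positive (camera adjusted p = 0.0277, and adjusted p = 0.932 with an estimated correlation). Adjusted over the list alone, 0 members passed in these 5 lists.

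None of these 5 lists passed without control 1. Their adjusted p was then 0.0638 for liver and pancreas, 0.355 for endothelial and stroma, 0.830 for erythroid, whose sign turned, 0.247 for muscle and 0.355 for stem and progenitor genes. The muscle list also did not pass without control 2 (adjusted p = 0.512) or il7 mutant 1 (adjusted p = 0.720), the erythroid list without il7 mutant 1 (adjusted p = 0.275), and the stem and progenitor list without control 3 (adjusted p = 0.249) or il7 mutant 1 (adjusted p = 0.135). The stem and progenitor list also did not pass with array quality weights (adjusted p = 0.183) or the filter at a mean of 50 (adjusted p = 0.0749), nor the liver and pancreas list with array quality weights (adjusted p = 0.0788). With both control 1 and il7 mutant 2 left out, only the erythroid list of these 5 passed (adjusted p = 0.00257). The count of 7 passing lists also has to be set beside other groupings of the 6 libraries, which passed up to 15 lists.

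The libraries differed in transcripts of other tissues. Control 1 and il7 mutant 2 held 55927 and 31205 normalized counts of zp3b, an egg coat gene, where the other 4 libraries held between 52.1 and 68.7. The oocyte gene buc stood at 36716 and 17983 in that pair and between 27.0 and 67.7 in the others. As a median over genes, the muscle list was highest in il7 mutant 1 and control 3, at 2.32 and 1.75 log2 units above the mean of the libraries. By that measure the liver and pancreas list was highest in il7 mutant 2, at 2.38. Its summed normalized counts were highest in control 3, at 104726 against 72383 in il7 mutant 2. With control 1 and il7 mutant 2 left out, a choice made after seeing the data, limma called 0 genes, against 1092 at an unadjusted p under 0.05.

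**Figure D2:**
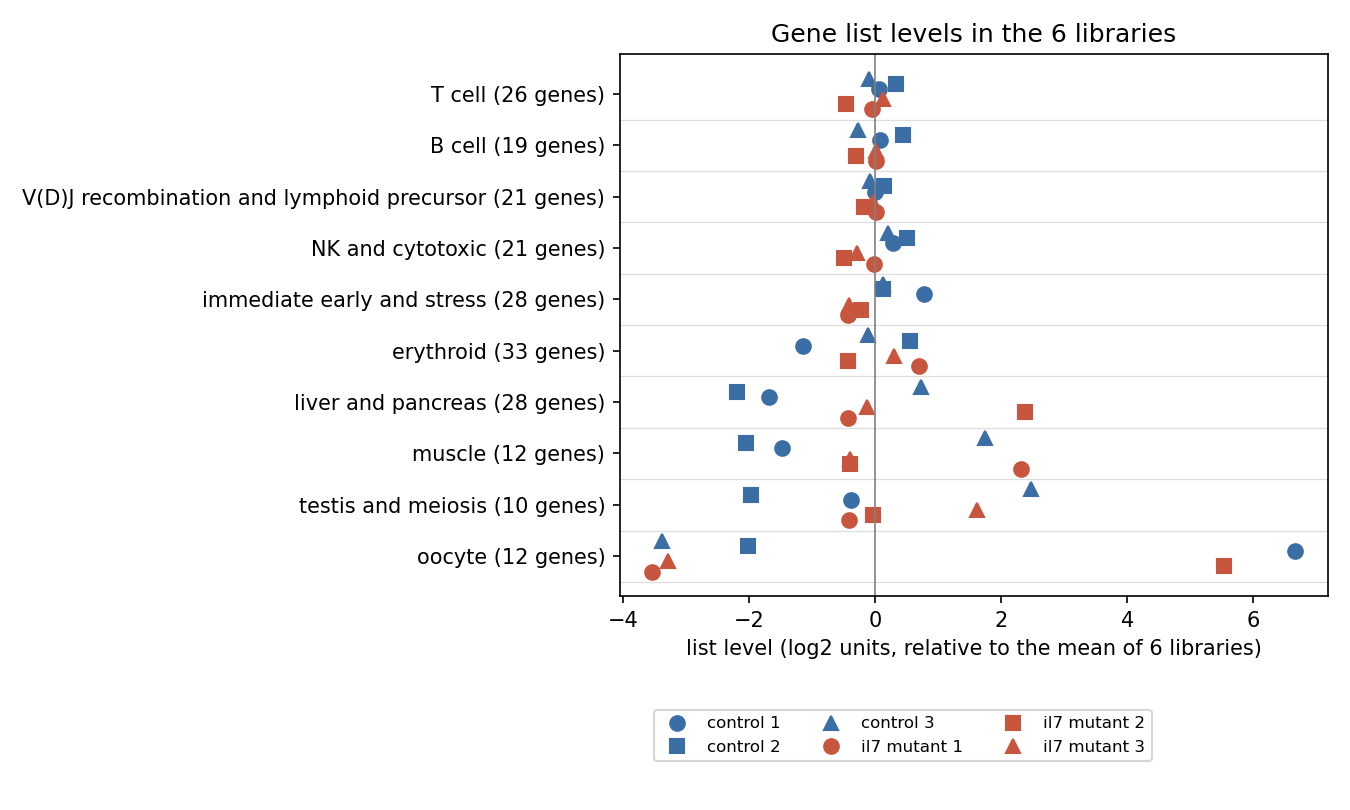
Level of 10 gene lists in each library, as the median over genes of log2(normalized count + 1) minus the gene's mean over the 6 libraries, with controls in blue and il7 mutants in red. The oocyte genes stand at 6.67 in control 1 and 5.54 in il7 mutant 2 and below 0 in the other 4 libraries, while the T cell, B cell and V(D)J lists overlap between the groups.

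The remaining lists did not pass with all 6 libraries, with adjusted p of 0.975 for kidney tubule and nephron, 0.968 for gonad and germ cell, 0.250 for cell cycle, 0.968 for interferon response, 0.913 for inflammatory cytokines and chemokines, 0.0813 for the nitr family of immune-type receptors, 0.616 for ribosomal proteins and 0.0991 for mitochondrially encoded genes. Ribosomal protein genes passed in opposite directions: lower without control 1 (adjusted p = 1.2e-18), without il7 mutant 1 (adjusted p = 0.00341), without both control 1 and il7 mutant 2 (adjusted p = 8.8e-08) and with array quality weights (adjusted p = 0.00475), but higher without control 2 (adjusted p = 0.0235). Mitochondrially encoded genes passed as higher with quantile normalization (adjusted p = 0.00545), with the oocyte-rich libraries as a model term (adjusted p = 0.00799) and without control 2 (adjusted p = 0.0128), control 3 (adjusted p = 0.0111) or il7 mutant 2 (adjusted p = 0.00640). The gonad list passed as higher without control 1 (adjusted p = 0.0474) and as lower without control 2 (adjusted p = 0.00424) or il7 mutant 2 (adjusted p = 0.0245). The cell cycle list passed as lower without control 3 (adjusted p = 0.0187) or il7 mutant 2 (adjusted p = 0.00128), the kidney tubule list as lower without control 1 (adjusted p = 0.00736) and the interferon list as higher without control 2 (adjusted p = 0.0493). The immune-type receptor list passed as lower with quantile normalization (adjusted p = 0.0439), with array quality weights (adjusted p = 0.0246) and without il7 mutant 3 (adjusted p = 0.0388). These calls use the preset correlation. With all 6 libraries and an estimated correlation, 0 lists passed.

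The median or the mean differed in sign from the test for the macrophage, kidney tubule, interferon and inflammatory lists.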

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

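Including the oocyte-rich libraries as a model term, and leaving both out, were chosen after seeing the data. So was using no filter together with an estimated correlation, with which 0 lists passed. Under all 19 alternatives for genes, limma called 0 genes, so 0 could be shared with the authors' deposited table. The il7 change stayed negative and short of the adjusted threshold wherever il7 was fitted, which it was not with the filter at a mean of 50. It lay between −2.89 and −1.93 with single libraries left out. The count at an unadjusted p under 0.05 was 723, and 1563 with array quality weights, 1672 with the oocyte-rich libraries as a term and 1092 without them. The 7 passing lists became 0 with an estimated correlation and 0 with fry, whose smallest adjusted p for change in one direction was 0.348. For change in either direction 1 list passed with fry, the gamma chain family cytokines, at an adjusted p of 0.0389. That list holds il7, the deleted gene, so its result partly follows from the design. With single libraries left out between 6 and 11 lists passed: 11 without control 2, il7 mutant 2 or il7 mutant 3. The immediate early and the natural killer lists passed as lower in 17 of 19 alternatives, failing with an estimated correlation and with fry. The cause was not tested.

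Of 2154 comparisons of 115 named genes with their first value, 2130 kept the sign and the side of the threshold and 24 turned sign, in 11 genes, none of which passed in any setting. With quantile normalization the genes that turned sign were RAG2 (0.034) and lck (0.0022), and with array quality weights f5 (−0.022), ighm (0.0049) and lck (0.24). Without both oocyte-rich libraries they were SLC26A1 (−0.26), cd79a (0.14), f5 (−0.085), il2rb (0.15), trbc1 (0.055) and lck (0.27). With single libraries left out the changes ran from −0.32 to 0.25 for RAG2, −0.37 to 0.34 for lck, −0.48 to 0.30 for cd79a, −0.38 to 0.24 for RAG1, −0.20 to 0.029 for stat5b, −0.51 to 0.086 for il2rb, −0.83 to 0.043 for stat5a and −0.53 to 0.029 for trbc1. The cause was not tested.

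The replicate block gave 0 genes and 6 lists, as the stem and progenitor list did not pass (adjusted p = 0.0706). Same-numbered libraries had correlations of their deviations from the group means of −0.51, −0.40 and 0.51. The highest correlation, 0.73, was between the oocyte-rich libraries, control 1 and il7 mutant 2. Their shared structure weighs on these values, so they cannot decide whether the numbers pair the samples. The 2 planned count tests on recovered reads were not run. In simulated data limma recovered 0 of 66 changes of 2-fold with each gene's own spread and 7 of 66 with the median spread. Most changes of that size may thus be missed here. The simulated genes were drawn independently, while those of the real libraries share a structure, so these shares are only a guide.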

Other observations

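The tests of explanations in this part, and the leaving out of control 1 and il7 mutant 2 together, were chosen after the results were seen. The meiosis gene sycp2 stood at 655 normalized counts in control 3 and 270 in il7 mutant 3, against 0 to 41.6 in the other 4 libraries, and SYCP3 at 653 and 242. The MHC class II genes mhc2dga and mhc2dgb stood between 724 and 1474 in 4 libraries and at no more than 1 in control 1 and il7 mutant 2.

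With 3 samples against 3 there are 10 splits, too few for a share under 0.05. For genes past the adjusted threshold, the real split gave 0, so 10 of 10 splits gave as many, and the highest other gave 44. That split put control 1, control 2 and il7 mutant 2 together. The 4 splits that keep the oocyte-rich pair together gave 44, 2, 0 and 0 genes, and the other splits gave 0. At an unadjusted p under 0.05 those 4 gave between 1529 and 3774 genes, which points to a structure of the samples. The real split, which parts the pair, gave 723, and the other splits that part it gave between 227 and 466. With both oocyte-rich libraries left out, 0 genes were called. For the set test the real split passed 7 lists, 9 of 10 splits passed as many, and the highest other passed 15.

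Control 1 and il7 mutant 2 lay apart from the other libraries on the first principal component, which held 57.8% of the variance. Depth alone is argued against, since il7 mutant 2, at 35854285 reads, lay within the range of the other 4. The il7 genotype is also argued against, since the pair held 1 mutant. Oocyte RNA may be part of the source: 100% of the 12 fitted oocyte markers were at least 10-fold above the highest of the other libraries in both. Added RNA alone would not take other genes near 0. Yet mhc2dga and mhc2dgb stood at no more than 1 in this pair, against 724 to 1474 in the other libraries. What else the pair shares was not tested. The oocyte markers were picked from the gonad list after the values were seen, so their 10-fold excess was partly known in advance. They made up 0.61% of the summed normalized counts in control 1 and 0.29% in il7 mutant 2. Ovary lies near the kidney, but the tests do not show how such RNA came in.

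The immediate early and stress list was lower in the mutants, and the real split gave it the smallest set p of the 10 splits. The list was taken up after that p was seen, so the rank partly restates this choice, and 10 splits are too few for a share under 0.05. Oocyte RNA is argued against as the cause, since the list still passed as lower with control 1 and il7 mutant 2 left out (adjusted p = 1.3e-04; the range over the alternatives was 2.7e-07 to 0.357). A difference in handling or time to lysis could also lower such genes. On the list level, a median over genes, the lowest control lay 0.35 log2 units above the highest mutant. Summed normalized counts of the list overlapped, with control 1 at 177093 and il7 mutant 2 at 181257. Genotype would give such a gap as well as handling, so these cannot be told apart.

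The muscle and the liver and pancreas lists were higher in the mutants with the preset correlation only (adjusted p = 0.991 and 0.794 with an estimated correlation). Neither passed without control 1, or without both control 1 and il7 mutant 2 (adjusted p = 0.125 and 0.758). Uneven carry-over of those tissues between single libraries may account for this, as the muscle level ranged over 3.80 log2 units within the controls, against a difference of 1.096 between the group means. For liver and pancreas the range was 2.93, against 1.66. Genotype as a further contribution was not tested.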
